A study of Rattus norvegicus with 8 samples.

How the data were processed

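Total RNA from the right kidney of 4 sham-operated and 4 unilaterally nephrectomized female rats was extracted with a silica-column kit and labelled with Cy3 by a low-input amplification kit, per the labels' protocols. Each sample was hybridised to a 1-colour Agilent rat expression array, and the images were read with Agilent Feature Extraction 10.5.1.1, per the file headers. The authors deposited 1 scanner file per array. Its processed signal is an intensity on a linear scale, background-subtracted and detrended within the array and not normalized between arrays, per the file headers. The files also hold the raw median intensity of each spot and of its background, and flags of 0 or 1 for spots above background, saturated or marked as outliers, per the file headers. The deposited series table holds log2 values, which the labels do not describe. Set against the scanner values of the same arrays they correlated at over 0.999 with a slope of 1.00, which shows log2 values shifted to each array's 75th percentile and centred per probe on the median of the 8 arrays, in the same direction. Their column medians were -0.0145, -0.00231, -0.00103 and -0.00968 for sham replicates 1 to 4 and 0.00123, 0.0124, -0.000916 and 0.0153 for nephrectomized replicates 1 to 4. Nothing about their scale, centring or direction stayed unknown.

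Groups and replicate numbers were taken from the labels, which list the samples as separate without naming the animals, so p-values measure the spread between these samples. The arrays lay on 2 slides, each scanned in its own session and each holding 2 sham and 2 nephrectomized arrays. On both slides the sham arrays occupied positions 1 and 2 and the nephrectomized arrays positions 3 and 4, so position on the slide and group cannot be told apart. The number of arrays limits the precision.

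From the processed signal, log2 values were computed and each array's 75th percentile was subtracted. Of 45018 spots per array, 1639 control spots and the spots marked as outliers were left out, and spots of 1 probe were averaged, giving 41012 probes. A probe was tested when well above background on at least 4 of the 8 arrays, which 25250 probes met, and 25228 had a value on every array. Probes were named by matching their RefSeq accession, without version, to a table of RefSeq genes of assembly GRCr8. This matched 18713 probes, 13628 of them tested. The remaining probes keep the array's accession and are unnamed here. The array's headers name another rat assembly, so no coordinates are given. Each gene was represented by its probe with the highest mean over all arrays, which left 20935 features, 10240 of them with a symbol. The probes of a named gene disagreed in sign for Fbp1, Vwf, Hspd1 and Klf6, none of which was called.

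Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, nephrectomized minus sham, no covariates, 6 residual and 2.37 prior degrees of freedom), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A feature not well above background on any array of a group has no reliable level there. Its fold is the bright group's mean over the dim group's mean after a floor on the dim signals. The floor takes, per array, the higher of the lowest signal among probes well above background and the probe's own. Where the probe's own signal is the higher, this is the measured fold and not a lower bound. Gene lists for 33 pathways, nephron segments and other cell types, with 794 symbols of which 727 were on the array and 647 were tested, were compared by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fry's PValue tests whether a list's genes move on balance one way, and its PValue.Mixed whether they change in either direction, and neither compares the list with other genes. List means per array were compared by two-sided exact permutation over the 70 assignments of arrays, and their 95% intervals hold the shifts that this test does not reject.

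The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Named are the 10 largest increases and 10 largest decreases among called genes with a symbol that is not a placeholder and no overlap between groups, up to 3 called members of each list by smallest adjusted p or else the 2 brightest members, and 15 genes chosen for the kidney regardless of outcome. The alternatives were normexp background correction, quantile, median and cyclic loess normalization, 2 other filters on dim probes, 2 other rules for a gene's probes, trend and robust variance, array weights, replicate and slide as blocks, the deposited series table, and leaving out each array. The planned normexp setting named the mean spot signal, which the scanner files do not hold, so the median spot signal took its place, with an offset of 50.

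The steps were tested on simulated arrays with the real means and spreads of 20935 features and 200 changed features in each of 20 runs. Changes of 0.5, 1, 1.5 and 2 on the log2 scale were recovered in 49.9%, 86.0%, 95.0% and 96.9% of cases, with 4.88% false features among the calls. A list of 20 genes raised by 0.5 was found in 20 of 20 runs by each list test, and of 600 unchanged lists camera called 0 under either correlation and fry 7. Simulated genes vary independently, so this says nothing of lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.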

Results

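Gene expression was measured in the right kidney of 8 female F344/NSlc rats aged 10 weeks, 4 after a sham operation and 4 after unilateral nephrectomy, the removal of 1 kidney that leaves the other to take over its work. The comparison asks which transcripts differ in the remaining kidney early in this compensation. The study's design text places sampling 2 days after surgery for both groups, whereas the source names give 1 day for the sham kidneys and 2 days for the nephrectomized ones, and the values do not settle which is right. If the source names are right, day and operation cannot be told apart for any difference between the groups reported below. Each RNA was hybridised to its own 1-colour array, and between 59.5% and 66.1% of the 41012 probes on an array were well above background, with none saturated and a 75th percentile signal between 388 and 643. Pearson correlations between arrays, across probes that are not independent replicates, lay between 0.986 and 0.993.

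In the remaining kidney of nephrectomized rats 15 of 24 tested genes of cholesterol synthesis and uptake rose, as did 7 of 24 of DNA replication and 4 of 20 of G2 and mitosis, while the clock repressors Nr1d1 and Nr1d2 were among the genes that fell. Cdk1, the kinase that drives entry into mitosis, was 4.91-fold higher, and Idi1, an enzyme of the isoprenoid steps of cholesterol synthesis, was 2.90-fold higher. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, fell by 1.69 and 1.40 on the log2 scale. With limma, 157 of 20935 features were higher and 60 were lower at a Benjamini-Hochberg adjusted p under 0.05, of which 94 and 32 carry a gene symbol. At least 2-fold changes were found in 41 higher and 9 lower features. The sham and nephrectomized values did not overlap for any of the 217 called features, but the threshold, with 4 against 4 arrays, largely selects such features. Of all tested features 11.1% did not overlap, against 2.86% expected by chance. With slide as a block the counts were 69 higher and 31 lower, and on either slide alone, with 2 arrays per group, limma passed 0 features. At an unadjusted p under 0.05 there were 1882 on slide 1, 1740 on slide 2 and 3358 over all arrays. The number of calls depends on single arrays, with 22 features past the threshold without sham replicate 2 and 198 without nephrectomized replicate 1.

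**Figure D1:**
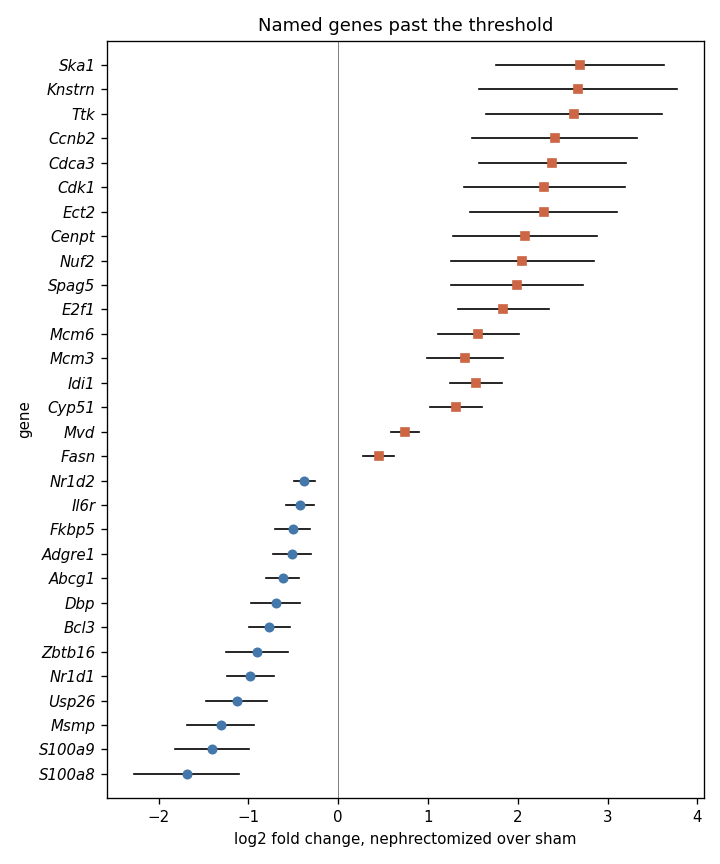
Log2 fold change, nephrectomized over sham, of a selection of named genes past the adjusted threshold, with limma's 95% interval as a line and 4 arrays per group. Ska1 and Knstrn are drawn at their measured values although no sham array measured them well above background; squares are higher and circles lower after nephrectomy, from 2.69 for Ska1 to -1.69 for S100a8.

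Of the 10 named genes with the largest increases, Ttk, Ccnb2, Cdk1 and Ect2 belong to the G2 and mitosis list, and the other 6 are outside the lists. Ska1 and Knstrn, which act at the kinetochore and spindle, were well above background on all 4 nephrectomized arrays and on no sham array. With the floor on dim signals their increases were 6.43-fold (limma adjusted p = 0.0361) and 6.35-fold (adjusted p = 0.0485) on the processed signal. The measured increases were 6.46-fold and 6.35-fold, so the floor changed little and these folds are not lower bounds. Limma's intervals reached down to 1.76 for Ska1 and 1.56 for Knstrn on the log2 scale. The sizes of the increases also depend on the background correction. Normexp with its offset gave log2 changes of 0.95 for Ska1, 1.04 for Knstrn, 1.45 for Ttk, 1.60 for Ccnb2, 1.28 for both Cenpt and Spag5 and 1.17 for Nuf2, all past the threshold, and a mitosis list median of 1.20. Ttk, a spindle checkpoint kinase well above background on 2 of 4 sham arrays, rose by 2.63 ± 0.43 (SE, log2; adjusted p = 0.0396), from -3.74 ± 0.49 in sham to -1.12 ± 0.88 in nephrectomized kidneys (SD, n = 4 each, log2 relative to the array's 75th percentile). The second, dimmer probe of Ttk was at 1.83 and did not pass with every probe tested on its own. Ccnb2, a B-type cyclin, rose by 2.41, Cdca3 by 2.38, Cdk1 by 2.30, Ect2, a cytokinesis factor, by 2.29, Cenpt by 2.08, Nuf2 by 2.05 and Spag5 by 1.99.

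Of the 20 tested genes of the G2 and mitosis list, all 20 had positive values, with a median of 1.93, and 4 passed the threshold over all genes, namely Ect2, Ttk, Ccnb2 and Cdk1. Adjusted over the list alone, 19 were higher. Mki67, a standard proliferation marker, was at 1.64 ± 0.35 (SE) with a limma adjusted p of 0.0670, just outside the threshold, and its groups did not overlap. The list was higher by limma's camera (adjusted p = 2.28e-17; adjusted p = 0.337 with an estimated correlation), with medians of 1.68 on slide 1 and 2.19 on slide 2. Nephrectomized kidneys differed widely among themselves, the list mean lying 0.79 above the sham mean in replicate 1 and 2.12, 1.60 and 2.66 above it in replicates 2, 3 and 4. The share of probes well above background ranked the nephrectomized arrays in the same way, at 59.5%, 63.4%, 61.6% and 66.1% for replicates 1 to 4, and it did so within the sham group too.

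DNA replication genes were also higher. Of 24 tested members, 7 rose over all genes tested and 17 when adjusted over the list alone, with none lower. E2f1, a transcription factor of the G1 to S transition, rose by 1.84 ± 0.22 (SE; limma adjusted p = 0.0151), and the replicative helicase subunits Mcm6 and Mcm3 rose by 1.56 (0.85 with normexp) and 1.41, in each case without overlap between the 4 sham and 4 nephrectomized arrays. The list median was 0.40 (camera adjusted p = 1.13e-14; adjusted p = 0.226 with an estimated correlation), 0.39 on slide 1 and 0.45 on slide 2. Ccnd1, which encodes cyclin D1, was at 0.08 ± 0.17, Myc at 0.14 ± 0.18 and the cell cycle inhibitor Cdkn1a at 0.25 ± 0.15 (SE), none past the threshold.

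Cholesterol synthesis and uptake genes formed the group with the most calls. Of 24 tested members 15 rose over all genes tested, and adjusted over the list alone 22 were higher and 1, Ggps1, was lower at -0.22. Idi1 rose by 1.54 ± 0.13 (SE; limma adjusted p = 0.0101), from 1.38 ± 0.12 to 2.92 ± 0.25 (SD, n = 4 each), and its 2 probes gave 1.54 and 1.46. Cyp51, the lanosterol demethylase, rose by 1.31 and Mvd, which makes isopentenyl diphosphate, by 0.74, both with an adjusted p of 0.0101. The list median was 0.63 (camera adjusted p = 2.65e-24; adjusted p = 0.150 with an estimated correlation), 0.55 on slide 1 and 0.78 on slide 2. In the fatty acid synthesis list, Fasn, the fatty acid synthase, rose by 0.45 (limma adjusted p = 0.0419), with 4 members higher when adjusted over the list alone, while the list itself was not called (median 0.07, camera adjusted p = 0.298).

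**Figure D2:**
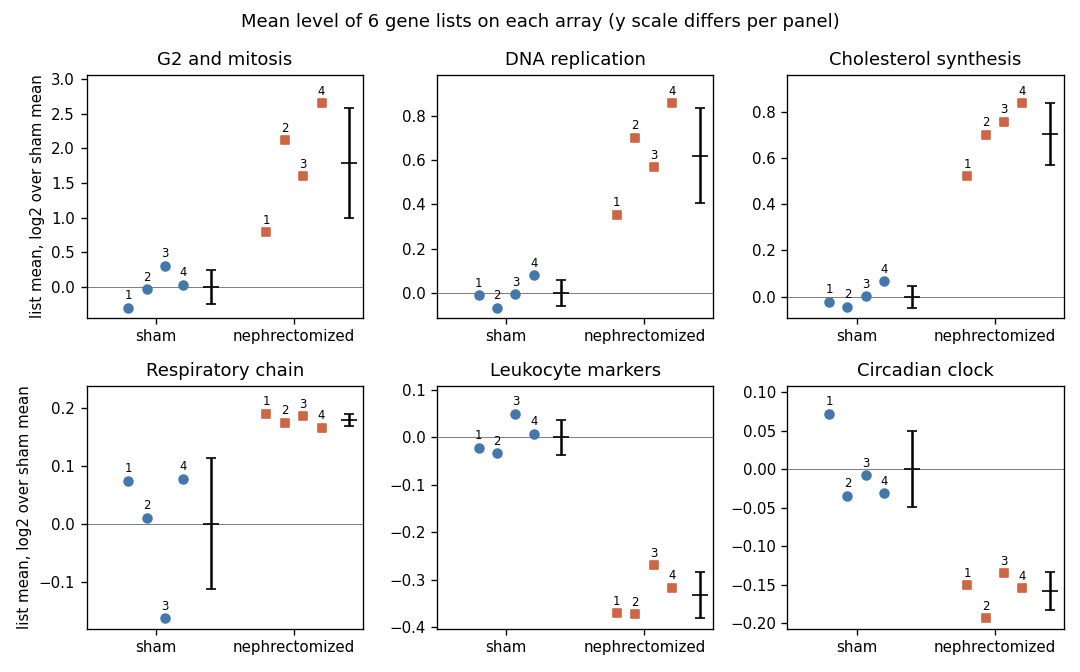
Mean log2 level of 6 gene lists on each array, relative to the mean of the 4 sham arrays, with circles for sham, squares for nephrectomized kidneys, replicate numbers beside the points, and the group mean ± SD to their right. The groups do not overlap in any of the 6 panels; the mitosis means of the nephrectomized arrays run from 0.79 to 2.66, and the y scale differs between panels.

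The respiratory chain list was higher by a small amount. None of its 31 members passed over all genes tested, 10 were higher when adjusted over the list alone, 30 had positive values and the median was 0.18 (camera adjusted p = 2.58e-09; adjusted p = 0.511 with an estimated correlation), 0.17 on slide 1 and 0.23 on slide 2. Interferon-stimulated genes had a median of 0.17 with no member called under either adjustment (camera adjusted p = 0.0129; adjusted p = 0.896 with an estimated correlation), with medians of 0.16 and 0.24 on the slides, and their list means per array overlapped between groups (exact permutation p = 0.229, two-sided, 4 against 4).

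Leukocyte markers were lower after nephrectomy. Of 18 tested markers 3 fell over all genes tested and 5 when adjusted over the list alone, and 16 had negative values. S100a9 fell by 1.40 ± 0.18 (SE; limma adjusted p = 0.0187), from -0.29 ± 0.29 to -1.69 ± 0.29 (SD, n = 4 each), S100a8 by 1.69 ± 0.25 (adjusted p = 0.0358; -1.02 with normexp, and past the threshold in 13 of 21 alternatives that use both slides) and Adgre1, which encodes the macrophage antigen F4/80, by 0.51 ± 0.09 (adjusted p = 0.0476). The list median was -0.21 (camera adjusted p = 2.36e-06; adjusted p = 0.150 with an estimated correlation), -0.20 on slide 1 and -0.19 on slide 2. Without S100a8 and S100a9, left out after their values were seen, the median was -0.18 (camera adjusted p = 0.000253; adjusted p = 0.350 with an estimated correlation). Complement and acute phase genes had a median of -0.24 (camera adjusted p = 1.47e-04; adjusted p = 0.226 with an estimated correlation), -0.25 on slide 1 and -0.14 on slide 2, and of 20 tested members only Il6r, an interleukin 6 receptor subunit, passed, falling by 0.43 (-0.17 and not past the threshold with normexp), over all genes and when adjusted over the list alone.

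Clock genes changed in both directions. Nr1d1 and Nr1d2, which encode the REV-ERB repressors, fell by 0.98 ± 0.12 and 0.38 ± 0.05 (SE; limma adjusted p = 0.0143 and 0.0246), and Dbp, a clock output factor, fell by 0.70, without overlap between groups. Adjusted over the list alone, 7 of 15 members were lower and 2 were higher, and the list median was -0.17 (camera adjusted p = 0.0103; adjusted p = 0.226 with an estimated correlation), -0.19 on slide 1 and -0.15 on slide 2. In the glucocorticoid-responsive list, Zbtb16 fell by 0.91 and Fkbp5 by 0.51, with 5 of 16 members lower when adjusted over the list alone and 8 on each side of 0. Its median was -0.08 (camera adjusted p = 0.0297; adjusted p = 0.744 with an estimated correlation), -0.11 on slide 1 and -0.14 on slide 2. Under the alternatives that use both slides this median lay between -0.31 and -0.0085. The second probe of Zbtb16 was at -0.45 and the other probes of Fkbp5 at -0.49 and -0.37. None of these passed with every probe tested on its own. Endoplasmic reticulum chaperones had a median of -0.09 with no member called under either adjustment (camera adjusted p = 0.0341; adjusted p = 0.896 with an estimated correlation), and the median was -0.20 on slide 1 and 0.05 on slide 2.

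Outside these lists, the named decreases included Msmp, which fell by 1.31, Usp26 by 1.13, Bcl3, a regulator of NF-kappa-B, by 0.77 and Abcg1, a sterol exporter, by 0.62, each with a limma adjusted p under the threshold and no overlap between the 4 and 4 arrays. Usp26 was well above background on 3 of the 4 nephrectomized arrays and was at -0.41 with normexp.

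Transporter and segment markers of the nephron were not called. The 31 proximal tubule genes had a median of 0.00 and the 29 genes of the distal nephron one of 0.08, with camera adjusted p of 0.656 and 0.107. Slc34a1, the proximal sodium-phosphate cotransporter, was at -0.16 ± 0.08, Aqp2, the collecting duct water channel, at 0.14 ± 0.13, Umod at 0.03 ± 0.14, Kl at 0.08 ± 0.07 and Pck1 at 0.02 ± 0.13 (SE). Tubular injury markers had a median of 0.00 (camera adjusted p = 0.856). Havcr1 was well above background on 0 of 4 sham and 1 of 4 nephrectomized arrays, and Lcn2 on 1 of 4 in each group, so neither was tested. Among growth factors, Egf was at 0.08 ± 0.07 and Igf1 at 0.20 ± 0.34 (SE), with a list median of -0.05 (camera adjusted p = 0.492). The vasoactive list had a median of 0.05 (camera adjusted p = 0.737). Odc1, which starts polyamine synthesis, was at 0.00 ± 0.35 (SE).

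The other lists were not called by camera either. Ribosome biogenesis had a median of -0.07 (adjusted p = 0.0617), ATF4 targets 0.09 and NRF2 targets 0.06 (adjusted p = 0.298 for both), extracellular matrix -0.01 (adjusted p = 0.333), fatty acid oxidation 0.05 and HIF-responsive genes 0.05 (adjusted p = 0.552 for both), and heat shock proteins -0.01 (adjusted p = 0.661). Polyamine turnover had a median of -0.02 (adjusted p = 0.810), and gluconeogenesis 0.02, immediate early genes 0.03 and vitamin D, phosphate and calcium handling 0.03 (adjusted p = 0.856 for each). Markers of endothelium had a median of 0.04 (adjusted p = 0.552), podocytes -0.02 (adjusted p = 0.842), stroma 0.02, fat and adrenal gland 0.06 and urothelium and inner medulla 0.01 (adjusted p = 0.856 for each), and erythroid cells 0.00 (adjusted p = 0.915). For the proximal tubule, gluconeogenesis, endothelium and stroma lists the median was positive while camera's direction was down, with a mean of -0.03 for proximal tubule and endothelium, 0.01 for gluconeogenesis and 0.04 for stroma. The vitamin D list had a mean of -0.02 against a positive median and direction, and the erythroid list a mean of 0.03 against a negative median and direction. Over all genes tested Fasn was the only called member of the lists that camera did not call. Adjusted over the list alone, 3 HIF-responsive genes were higher and 1 lower. So were 2 NRF2 targets, with 1 lower, and 2 tubular injury markers. The same adjustment gave 1 higher member each for distal nephron, fatty acid oxidation, vasoactive genes, stroma and urothelium. It gave 1 higher and 1 lower for growth factors, gluconeogenesis and vitamin D, and 0 for the rest, fatty acid synthesis apart. The brightest members of lists without a called gene ranged from -0.41 for Herpud1, which acts in protein degradation at the endoplasmic reticulum, to 0.30 for Aldoa, a glycolytic enzyme, none past the threshold.

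Over the 33 lists camera with a preset correlation called 5 higher and 5 lower. None of the 10 calls held with an estimated correlation, under which 5 lists had an unadjusted p under 0.05. Of the 35 splits of the 8 arrays into 4 and 4, 11 called at least 10 lists, so the number of called lists does not set the real grouping apart. For the mitosis, replication, cholesterol, respiratory chain, leukocyte, complement and clock lists the list means per array separated the groups fully (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 allows, before adjustment over the 33 lists). Fry, whose p tests whether a list's genes move on balance one way without comparing them with other genes, called the mitosis, replication and cholesterol lists higher and the leukocyte and clock lists lower. Fry's PValue.Mixed, adjusted over the lists, also passed for some lists that camera did not call. Among them were growth factors (5.13e-05), fatty acid synthesis (6.23e-05), gluconeogenesis (0.000300), HIF-responsive genes (0.000679) and tubular injury (0.00119). It did not pass for proximal tubule (0.708) or heat shock proteins (0.887), among others.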

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

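The tests of residual blood, of the day of sampling and of macrophage genes were chosen only after the result was seen.

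Leukocyte markers were lower after nephrectomy, with a list median of -0.21 (camera adjusted p = 2.36e-06; adjusted p = 0.150 with an estimated correlation). Less residual blood in the nephrectomized kidneys could lower them, but the red cell genes Hbb, Alas2 and Ahsp had a mean change of 0.096 (95% interval -0.248 to 0.451). This interval reaches below the leukocyte median but not the list mean of -0.333, on which S100a8 at -1.69 and S100a9 at -1.40 weigh. Blood content therefore stays open. Fewer leukocytes of every type are a candidate explanation, since 7 tested pan-leukocyte genes had a mean change of -0.194 (exact permutation p = 0.0286, two-sided) and 5 of them were negative. All 7 also belong to the leukocyte list, Coro1a and Aif1 were at 0.01 and 0.05, and 7 macrophage genes had a mean change of -0.100 (interval -0.294 to 0.171) with all 7 negative, beside the called macrophage gene Adgre1 at -0.51, so whether every type fell stays open. The day of sampling cannot be told apart from the operation if the source names are right, because 0 sham arrays carry the nephrectomized arrays' day, and an effect of nephrectomy itself also stays open. The same limit holds for every other difference between the groups.

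Nr1d1, Nr1d2 and Dbp were lower after nephrectomy. If kidneys of the groups were taken at different times of day, genes of the opposite clock phase (Bmal1, Npas2, Clock, Nfil3 and Cry1) should be higher. All 5 had positive values with a mean of 0.269, but its interval of -0.028 to 0.572 includes 0 (exact permutation p = 0.0857). Nr1d1 and Nr1d2 encode clock repressors, so such a rise could also follow from their fall, whatever its cause. Such a rise would therefore not single out time of day. A lower glucocorticoid response may also lower clock outputs. The 13 other glucocorticoid-responsive genes had a mean change of -0.00973 (interval -0.540 to 0.416), too wide to decide. Of these, 6 were negative, among them Klf9 at -0.35, Mt2A at -0.33, Mt1 at -0.32 and Tsc22d3 at -0.25, each with an unadjusted limma p under 0.05. The 7 positive ones, the largest Ddit4 at 0.77 ± 0.55 (SE), did not reach that p. None of the 13 passed the adjusted threshold. The labels give no time of day, so both stay open beside an effect of the operation.

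Mitosis genes were lower in nephrectomized replicate 1 than in the other 3 nephrectomized arrays, by a mean of -1.34 with 19 of 20 members below all 3. That array also had the lowest share of probes well above background, 59.5%, and within each group this share ranked the arrays as the mitosis list did. Weaker signal of dim probes in general is argued against as the whole of it. Among 10000 random gene sets matched on mean expression, the median deviation on that array was -0.027 and the central 95% ran from -0.148 to 0.115. Genes of like brightness were thus not lower there by a comparable amount. That the mitosis list lay outside this range adds nothing, because the array was picked for its low mitosis genes, which vary together (estimated correlation 0.87). Fewer cells in S phase and mitosis in that kidney may account for it. The replication list, which shares no gene with the mitosis list, was also lower there by a mean of -0.354. None of 10000 matched sets was as low. Matched sets hold unrelated genes, whereas the replication genes vary together (estimated correlation 0.40), and the array was picked for its low mitosis genes. The comparison therefore cannot decide this explanation. The design names no difference between the 4 nephrectomized rats, so no biological explanation of this spread was tested beyond that.

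Among 296 groups of 4 values checked for 1 sample standing apart, 16 did, where chance gives about 5%. In sham replicate 1 Ect2 stood at -2.79 against -2.38 to -2.31 in the other sham arrays, Adgre1 at -0.81 against -0.66 to -0.63, Col1a2 at 3.60 against 4.09 to 4.19, Tubb2b at 4.62 against 5.09 to 5.18, and the stroma list at -0.0837 from the sham mean. In sham replicate 2 Coro1a stood at 2.41 against 2.73 to 2.75. In sham replicate 3 Npm1 stood at 5.18, Tkt at 7.33 and Fbp1 at 8.47, each below the other 3. In sham replicate 4 Klk1 stood at 7.53. In nephrectomized replicates, the chaperone list stood at -0.192 in replicate 1, Ndrg1 at 5.57 in replicate 2, and Npm1 at 5.18 in replicate 3. In replicate 4 Igf1 stood at 3.45 against 2.89 to 2.95, the NRF2 list at -0.158 and the endothelium list at 0.00526.

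Of 4353 probes left out of the test because they were above background on 1 to 3 arrays, 112 were above it on 3 nephrectomized arrays and no sham array, against 28 the other way. Those with a symbol, 46 in number, included Cenpa, Cdt1, Tacc3, Pole2 and Gins3, which act in replication or mitosis, have no other tested probe and were singled out after their values were seen. The share of all probes well above background was 59.5%, 63.4%, 61.6% and 66.1% in nephrectomized replicates 1 to 4. In sham arrays it lay between 61.1% and 62.4%. The counts of 112 and 28 were not adjusted for these shares.

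Of the 35 splits of the 8 arrays into 4 and 4, only the real one reached 217 features past the threshold. The highest other split gave 1. A rank of 1 in 35 is the most extreme that 4 against 4 allows. The other splits mix both groups, so a real difference widens their spread and lowers their counts. For the genes the real grouping stood apart, but chance assignment of arrays was not excluded. For at least 2-fold changes likewise 1 of 35 splits reached the real 50, and the highest other gave 1. For the gene lists the real grouping did not stand apart, since 11 of 35 splits called at least the real 10 lists, with a highest other of 13.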

How the results depend on the processing

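The fits on each slide alone and the leukocyte list without its leading members were chosen after the data were seen. All 217 called features kept their sign under every alternative that tested them, which in fits with arrays left out follows from groups that do not overlap. Scaling choices moved the median of all features by under 0.05 and the share of higher calls by under 10 percentage points. The counts of genes higher after nephrectomy and genes lower after nephrectomy were 157 and 60 features, named or not (genes higher after nephrectomy by at least 2-fold 41, lower 9). Trend and robust variance gave 398 and 132 (69 higher at least 2-fold), array weights 384 and 118 (71), and probes above background on all 8 arrays 295 and 98. No filter on dim probes gave 17 and 3 (12 and 1), with more features tested. Normexp, whose offset shrinks dim signals, left 2 features at least 2-fold lower. The slide block gave 69 and 31, and each slide alone gave 0 in all 4 counts. Leaving out 1 array gave 18 to 163 higher and 4 to 35 lower features, 11 to 84 and 1 to 10 at least 2-fold. Without nephrectomized replicate 1 they were 163 and 35, without replicates 2 to 4 of that group 34 and 10, 27 and 8, and 35 and 10, and without sham replicates 1 to 4 39 and 13, 18 and 4, 25 and 8, and 41 and 14. The cause of these differences was not tested. With the replicate number as a block 6 features were higher and 4 lower, all at least 2-fold. Deviations of same-numbered arrays correlated at 0.14, 0.01, -0.06 and -0.21, and only replicate 1 matched best both ways. The values thus give no sign that the numbers pair the samples, and whether they do stays unknown.

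Of the 5 higher and 5 lower lists, 0 and 0 passed with an estimated correlation and 3 and 2 with fry. Slide 2 alone called 2 lists lower, and leaving out 1 array called 4 to 7 higher and 3 to 7 lower, the 3 without nephrectomized replicate 1. The cholesterol, mitosis, replication and leukocyte lists kept their call in 22 of 23 alternatives and lost it with the estimated correlation, whereas interferon lost it in 6 and the chaperone and glucocorticoid lists in 5. The clock list lost it in 3, its median lying between -0.21 and -0.03, and the respiratory chain and complement lists lost it in 2 each. Ribosome biogenesis gained a call in 9 of the 23, the distal nephron in 5, and proximal tubule, heat shock and NRF2 targets in 1 each. The chaperone list reversed on slide 2 alone, with a median of 0.0487; the cause was not tested. These counts leave out each slide alone, where 0 features passed with limma. On the same terms Idi1 stayed past the threshold in 21 of 21 alternatives, Cyp51 in 20, S100a9 in 15, Cdk1 in 11 and Adgre1 and Il6r in 9, and Mki67 passed in 4. Signal over background limits genes such as Ska1 and Ttk, which lay near background in sham kidneys.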

Other observations

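The test of macrophage genes was chosen only after the result was seen, and the tubulin and lymphocyte groups were chosen after their values were seen. No test was run of either group as a whole. Of 9 tested alpha and beta tubulins 7 rose with limma, among them Tubb5 by 0.59 (adjusted p = 0.0101), Tubb6 by 0.61 (0.40 and not past the threshold with the mean of its probes) and Tuba8 by 0.68, while Tubb2b was at 0.66 and Tubb3 at -0.24, neither past the threshold. The family median was 0.52 and lay between 0.49 and 0.59 under all alternatives. Tfrc, the transferrin receptor that takes up iron, rose by 1.41 (adjusted p = 0.0101), and Chek1, a DNA damage checkpoint kinase, by 1.25 (adjusted p = 0.0138; 0.51 with normexp), without overlap between the 4 and 4 arrays; both were also singled out after their values were seen.

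Of 8 tested genes of cytotoxic lymphocytes 4 fell, 4 did not pass, and 7 of the 8 had negative values. The chemokine Ccl5 fell by 0.49 and the granzymes Gzma, Gzmk and Gzmm by 0.50, 0.60 and 0.51 (limma adjusted p = 0.0383, 0.0385, 0.0414 and 0.0470), each without overlap between groups. With normexp Gzma and Gzmk were both at -0.29 and did not pass, and each passed in 10 of 21 alternatives that use both slides. Prf1 and Nkg7 were at -0.36 and -0.35 and did not pass. The median of the 8 tested genes was -0.42, between -0.47 and -0.29 under all alternatives.

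The sterol exporter Abcg1 and Mylip, which targets the LDL receptor for degradation, fell by 0.62 and 0.35 while cholesterol synthesis genes rose, and Abca1 was at -1.03 (limma adjusted p = 0.0827). All 3 genes are targets of the sterol sensor LXR, and lower LXR activity was put forward as a hypothesis and tested on 11 other targets whose values had not been looked at. The 6 that could be tested (Nr1h3, Lpcat3, Smpdl3a, Pltp, Apoe and Lpl) had a mean change of -0.00625 (95% interval -0.0863 to 0.0897), with 2 negative (Apoe at -0.43 and Pltp at -0.26) and 4 positive (among them Lpl at 0.30 and Lpcat3 at 0.25), none past the threshold, which leaves the hypothesis without support and undecided. Fewer macrophages stay open as a cause of the lower Abcg1, since 7 macrophage genes had a mean change of -0.100 (interval -0.294 to 0.171), above the change of Abcg1, and -0.152 with Adgre1 added (interval -0.348 to 0.124), whereas Adgre1 alone fell by 0.51.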
